A study of Mus musculus with 8 samples.

How the data were processed

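RNA of mouse heart ventricle was measured on 8 single-colour (Cy3) oligonucleotide arrays from Agilent, all on 1 slide and read in 1 scan. Per the labels, the ventricles of 3 animals were combined, RNA was extracted with TRIzol, and 100 ng was labelled with a one-colour kit. The labels gave 4 groups of 2 arrays: wild type (WT) and homozygous Tnnt2 ΔK210 knock-in (KI) mice, each at birth (0 day) and at 1 week. They did not say whether the 2 arrays of a group came from separate pools, so every error and p measured the spread between these arrays, which may be technical. All birth arrays lay in row 1 of the slide and all 1-week arrays in row 2, so age and row cannot be told apart. At birth the WT arrays lay in columns 1 and 2 and the KI arrays in columns 3 and 4, so genotype and column cannot be told apart there.

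The deposited scanner files held the processed signal of each spot as intensity on a linear scale, which the authors' scanner software had corrected for background and spatial trend within the array, with no normalization between arrays. The raw median spot and local background intensities and the flags of the deposited files were used for alternatives and filters; per the file headers the flags (other) were coded 0 and 1. The file headers gave Feature Extraction version 11.0.1.1 and genome build mm9, whereas the submitters' notes gave version 9.1. The deposited value table held the same processed intensity, averaged over the spots of a probe and without control probes.

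The columns of the value table were checked against the scanner files over all probes with 1 spot, at a relative tolerance of 0.0001. Each column equalled the scanner file of 1 sample, but 3 of the 4 columns at 1 week equalled the file of another sample. The 4 arrays at 1 week are therefore called A to D. Array A was WT replicate 1 in both records. Array B was WT replicate 2 by its scanner file and KI replicate 1 by the value table. Array C was KI replicate 1 by its scanner file and KI replicate 2 by the value table. Array D was KI replicate 2 by its scanner file and WT replicate 2 by the value table. The 4 birth arrays had the same sample in both. The scanner-file record was the design fixed before the data were examined. The value table was also planned as another source of values, and each comparison was made with its samples too. That these differ from those of the scanner files was found in the data, and the further alternatives run within the value-table record were added after seeing the data; no array was assigned by its expression values.

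Each array had 62976 features, of which 59305 were not controls. They covered 56605 probes, 300 of them with several spots, which were averaged without outlier spots; 15 probes with no usable spot were dropped. Gene symbols were taken from RefSeq accessions in the GRCm38.p6 table, which named 32994 probes of 22911 genes. The 23611 probes without a symbol entered only an added alternative. Because the build of the files differed from that of the gene table, only gene names, chromosomes and gene order were used.

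Signals were log2 transformed, and the 75th percentile of the array's non-control probes was subtracted. The brightest probe stood for each gene, and a gene was tested if it was well above background on both arrays of at least 1 group. This left 15757 genes in the scanner-file record and 15744 in the value-table record. Linear models with a mean for each group were fitted to all 8 arrays with limma 3.58.1 (lmFit and eBayes; R 4.3.3), with 4 residual degrees of freedom. The 5 comparisons were KI against WT at birth, KI against WT at 1 week, the difference between these (age by genotype), and 1 week against birth in WT and in KI. Benjamini-Hochberg adjustment was made in each comparison, with a threshold of 0.05. Values after ± are limma standard errors. With 2 arrays a group, no exact permutation test could pass the threshold, and no group was large enough for counting other splits of the samples. In a test on simulated data, known changes were added to genes at birth; limma recovered 68 of 100 genes changed 2-fold and 93 of 100 changed 4-fold in the scanner-file record, calling 7 unchanged genes. In the value-table record it recovered 49 and 99 of 100, calling 5 unchanged genes.

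The genes named were set by a rule fixed before the data were examined. It took Tnnt2, a panel of 20 cardiac genes, up to 8 genes in each direction in each genotype comparison, up to 5 in each direction in the others, and up to 3 members of each list. Genes past the threshold came first, and the smallest p filled the remaining places. Clone, predicted, Riken and accession names were left out of the places by direction, as were olfactory, vomeronasal, immunoglobulin and histone cluster genes. Some genes that the rule names are not reported here. The 14 functional lists covered cardiac stress and fetal genes, sarcomere, calcium handling, ion channels, fatty acid oxidation, glycolysis, oxidative phosphorylation, extracellular matrix, cell cycle, hypoxia, the integrated stress and unfolded protein responses, neurohormonal signalling, inflammation and interferon-stimulated genes. The 17 marker lists covered cardiomyocyte, atrial, fibroblast, endothelial, mural, macrophage, neutrophil, lymphocyte and thymus, erythroid, platelet, epicardial, Schwann and neural, lung epithelium, skeletal muscle, adipocyte, liver and sex-linked genes. The sex-linked list joins Xist to genes of the Y chromosome, which move in opposite directions with sex, so its median was not used here. Of the listed names, 11 had no probe. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which tests whether a list moves on balance without comparing it with other genes, were run beside it. A fold against a group below background was computed against the background level and is given as at least that fold. Such a bound belongs to the processed signal. Of 60 bounds over all comparisons and both records, 57 were not reached with normexp, and 15 were not reached under 1 or more of the other alternatives. The normexp alternative changed the background correction, added 50 to each signal, and changed the normalization and the spot signal used. The difference therefore cannot be put down to any single step.

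The alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization alone, scaling to the median, other filters on dim probes, an eBayes trend, array weights, the mean of a gene's probes, only the arrays compared, a replicate block, a 2-fold threshold and leaving out each array in turn. Normexp used the median spot signal in place of the mean, which was not used here. A slide or row block was not run, since there was 1 slide and a row held 1 age. Residuals of arrays with the same replicate number were not alike in all group pairs, so the numbers were not taken to pair samples. Replicate differences correlated between groups from -0.155 to 0.282 in the scanner-file record and from -0.137 to 0.285 in the value-table record. Scaling to the median moved all genes by up to -0.158 (log2, WT 1 week against birth, value-table record) and 0.145 (age by genotype, value-table record), and by -0.102 in WT with the scanner-file record; in the other comparisons the shift was at most 0.086 in size. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.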

Results

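The series compared gene expression in the heart ventricle of WT mice and of KI mice, which carry a deletion of lysine 210 in both copies of Tnnt2, the gene for cardiac troponin T of the thin filament. The knock-in is a model of inherited dilated cardiomyopathy, and the arrays sampled it at birth and at 1 week, with 2 arrays in each of 4 groups. The 75th percentile of signal lay between 621 and 652 on the birth arrays and at 715, 732, 658 and 465 on arrays A, B, C and D at 1 week. Between 60.7% and 64.7% of probes were well above background, and the number of arrays limits the precision of every value. The scanner software's quality check marked KI birth replicate 1 for evaluation and every other array as in range. The first principal component held 60.6% of the variance and parted the ages; the second held 11.8% and set array D apart. The deposited scanner files and the deposited value table gave different samples for arrays B, C and D, so each comparison involving 1 week was made in both records.

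Tnnt2 transcript was at a similar log2 level on every array, in units relative to the array's 75th percentile. It was 8.16 and 8.30 in WT at birth, 8.19 and 8.11 in KI at birth, and 8.33, 8.21, 8.20 and 7.77 on arrays A to D. KI minus WT for Tnnt2 was -0.08 ± 0.17 at birth; at 1 week it was -0.28 ± 0.17 in the scanner-file record and +0.15 ± 0.19 in the value-table record. The probe measures transcript level and does not read the deleted residue, so these values do not check the genotype of any array.

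KI against WT at birth asked which transcripts differed in the newborn heart. Interferon-stimulated genes, the antiviral response set, lay higher in KI as a group: 32 of 34 measured members had positive values and the median was +0.32 (log2, n = 2 arrays a group). Examples were Usp18, which removes the ubiquitin-like modifier Isg15 (+1.00 ± 0.11), the RNA sensor Oas2 (+0.85 ± 0.13) and the transcription factor Irf7 (+0.52 ± 0.11). No member passed over all genes (adjusted p for Usp18 = 0.345 in limma), and 4 were higher adjusted over the list alone. The list passed with camera (adjusted p = 5.0e-17) but not with an estimated correlation (adjusted p = 0.0735 with an estimated correlation), and fry gave adjusted p = 0.0206. Of the marker lists at birth, neutrophil (median +0.58), platelet (+0.47), lymphocyte and thymus (+0.41) and epicardial markers (+0.28) passed with camera, with adjusted p from 0.168 to 0.599 with an estimated correlation. Macrophage (+0.25; 0.106) and erythroid markers (+0.22; 0.135) did not pass, and no member of any marker list passed over all genes. Among neutrophil markers, S100a8 stood at +0.90 ± 0.31, S100a9 at +0.83 ± 0.26 and Retnlg at +1.17 ± 0.31.

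Single genes that parted the genotypes at birth included the aspartic protease Ctse, the adhesion molecule Cntn2, the endosomal GTPase Rab7b, the calcium channel Trpv6, the secreted protein Wfdc18 and the potassium channel Kcnc2. The birth arrays are the same in both records, but the spread is pooled over all groups, so the tests differ. In the value-table record these 6 genes passed, and for each of them both KI arrays lay beyond both WT arrays. Ctse rose by 4.201 ± 0.30 (log2; adjusted p = 0.0265); it was below background in WT, which made it at least 4.53-fold higher by the processed signal, a bound not reached with normexp (+1.00; adjusted p = 0.346). Cntn2 rose by 1.64 ± 0.14 (adjusted p = 0.0265), while Rab7b changed by -1.82 ± 0.15, Wfdc18 by -2.02 ± 0.17, Trpv6 by -2.34 ± 0.20 and Kcnc2 by -1.86 ± 0.17. Trpv6 was above background on 1 WT array and no KI array, so it was at least 1.55-fold lower, which normexp did not reach (-0.28). Those that did not pass there included Chil1 (+1.22 ± 0.14), the renin gene Ren1 (at least 1.76-fold higher, but +0.24 with normexp), the growth factor Nrg1 (+1.00), the lysosomal GTPase Arl8a (-1.76), Bhmt (at least 2.28-fold lower, but -0.41 with normexp), Cst6 (-1.11) and Siglech (-1.105). Of the genes that the rule took by direction at birth, 8 lie on chromosome 1, as does Tnnt2: Arl8a, Chil1, Ren1, Cntn2, Rab7b, Ctse, Angptl1 and Neurl3, at 10, 22, 32, 41, 56, 57, 72 and 466 tested genes from it (GRCm38.p6 gene order). Chromosome 1 holds 889 of the genes tested in the scanner-file record, or 5.64%. Of the 10 genes called by genotype at either age in the value-table record, 5 lie on it.

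In the scanner-file record 0 of 15757 genes passed at birth with limma, and 677 had an unadjusted p under 0.05 against 788 expected by chance. By the value table, 6 of 15744 passed, 2 higher and 4 lower, with 741 at an unadjusted p under 0.05 against 787. Without WT birth replicate 1 or 2 or KI birth replicate 1 or 2 the count was 18, 29, 37 or 24 in the scanner-file record and 31, 37, 40 or 26 in the value-table record; without a 1-week array it was 0 and 1 to 4. Genes with the smallest p in the scanner-file record, none of which passed, were Usp18, Oas2, the lymphocyte gene Nkg7 and the antigen-presenting H2-Aa, both below background, then Ifitm6 (+0.87), Cysltr1 (+0.89), Neurl3 (+1.09) and Hydin (+1.21). On the lower side they were Trpv6, Wfdc18, Siglech, Bfsp2 (-1.04), Cd180 (-1.02), Chrm1 (-0.98), Angptl1 (-0.93) and Pcdhb10. The 6 genes called in the value-table record each lost the call under at least 6 alternatives. None kept it with the replicate block or with only the arrays compared. Adjusted p over the alternatives ranged from 0.00649 to 0.346 for Ctse, 0.0154 to 0.510 for Cntn2, 0.0106 to 0.107 for Rab7b, 0.0111 to 0.222 for Wfdc18, 0.00649 to 1.00 for Trpv6 and 0.0106 to 0.704 for Kcnc2.

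**Figure D1:**
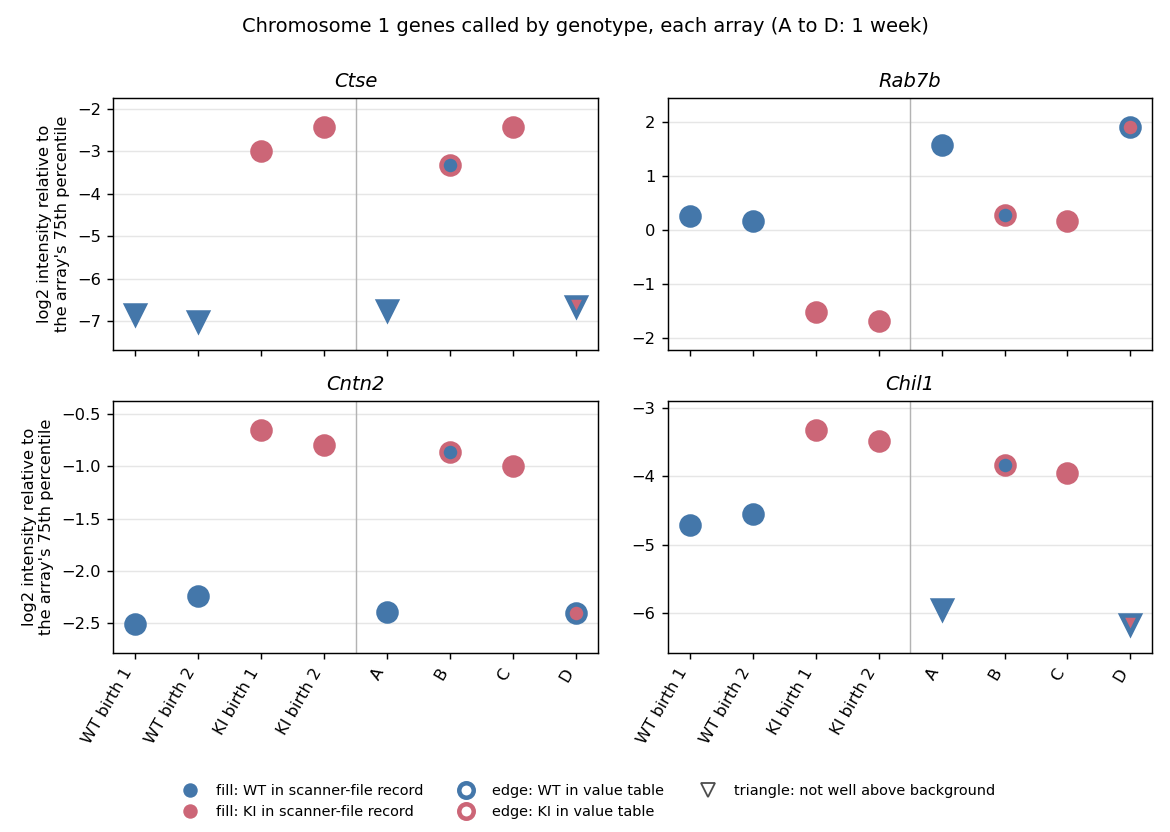
Log2 signal relative to the array's 75th percentile of Ctse, Rab7b, Cntn2 and Chil1, 4 of the 5 genes of chromosome 1 called by genotype in the value-table record, on each of the 8 arrays; fill gives the genotype by scanner file, edge the genotype by value table, and triangles mark spots not well above background. Ctse was at -2.99 and -2.44 on the KI arrays and -6.84 and -7.00 on the WT arrays at birth, and at -6.74, -3.32, -2.43 and -6.65 on arrays A, B, C and D.

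The other functional lists showed smaller differences at birth in the scanner-file record. Cell cycle genes had a median of -0.23, with 3 of 69 positive (camera adjusted p = 4.6e-05), and Mcm6, a subunit of the replicative helicase, stood at -0.71 ± 0.26. Oxidative phosphorylation genes had a median of -0.07 (2.7e-04), with Cox6c of the terminal oxidase at -0.66 ± 0.17, and inflammation genes +0.20 (0.00562), with the acute-phase genes Hp at +0.75 and Lcn2 at +0.61. No member of these 3 lists passed, and the adjusted p ranged from 0.627 to 0.651 with an estimated correlation. These calls depended on single arrays: without KI birth replicate 2 the cell cycle median turned to +0.12 and inflammation lost its call (0.0886). Without WT birth replicate 1 all 3 calls were lost (0.066 for cell cycle, 0.480 for oxidative phosphorylation and 0.066 for inflammation), and inflammation was also lost without array D (0.0536). The remaining 10 lists did not pass. Their medians were +0.12 for cardiac stress and fetal genes, +0.04 for sarcomere, +0.08 for calcium handling, -0.05 for ion channels, -0.06 for fatty acid oxidation, -0.05 for glycolysis, -0.04 for extracellular matrix, +0.06 for hypoxia, +0.07 for integrated stress and +0.07 for neurohormonal signalling. Under the value-table record calcium handling (0.0159), stress and fetal genes (0.0429) and hypoxia (0.0429) also passed with camera, with adjusted p from 0.216 to 0.660 with an estimated correlation. Each of these was lost without 1 or more single arrays, with an adjusted p of up to 0.226, 0.483 and 0.532. Without KI birth replicate 2 the medians there turned to -0.06 for hypoxia and +0.12 for cell cycle. Signalling genes with small p were the vasoconstrictor peptide Edn1 (+0.61 ± 0.15) and its receptor gene Ednrb (-0.70 ± 0.14), neither of which passed.

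None of the 20 panel genes passed at birth in either record. The natriuretic peptide genes were Nppa at +0.16 ± 0.70 and Nppb at -0.08 ± 0.29, and the myosin heavy chains were Myh7 at +0.02 ± 1.02 (±0.12 in the value-table record) and Myh6 at -0.22, with another Myh6 probe at 0.06; other probes of Atp2a2 (-0.04) and Col1a1 (-0.06) also pointed the other way. Transient outward potassium current genes stood at -0.94 ± 0.40 for Kcnip2 and -0.81 ± 0.41 for Kcnd2, the pacemaker channel Hcn4 at +0.56 ± 0.32 and the gap junction gene Gja1 at +0.41 ± 0.23. Calcium pump and release genes were close to 0, with Atp2a2 at +0.02, Pln at -0.03 and Ryr2 at -0.03. The rest were Acta1 (+0.27), Ankrd1 (+0.22), Postn (-0.46 ± 0.19), Col1a1 (+0.05), Tnni1 (+0.02), Tnni3 (-0.02), Ppargc1a (-0.20), Cpt1b (+0.00) and Mki67 (-0.37 ± 0.34).

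KI against WT at 1 week asked which transcripts differed in the young heart, and the answer depended on the record. With the value-table samples, Myh7, the slow myosin heavy chain of the fetal ventricle, rose by 2.62 ± 0.12 (log2; adjusted p = 0.00196; both KI arrays above both WT arrays). Casq1, the calsequestrin of fast skeletal muscle, rose by 2.68 ± 0.26 (adjusted p = 0.0414). Of the 8 genes of chromosome 1 taken by direction at birth, 4 passed in the same direction: Ctse (+3.82 ± 0.30, at least 3.70-fold higher), Chil1 (+2.15 ± 0.14, at least 1.82-fold), Cntn2 (+1.47 ± 0.14) and Rab7b (-1.52 ± 0.15), with adjusted p from 0.00747 to 0.0480. Arl8a kept its direction without passing (-0.80), and Ren1 (-0.86), Angptl1 (+0.18) and Neurl3 (-0.08) pointed the other way. The 4 that passed had been taken at birth in the value-table record, and Angptl1 and Neurl3 in the scanner-file record. The spread behind the p at birth was pooled with these same 1-week groups. A gene with little spread there is favoured at both ages, so passing again is not independent support. Kcnc2 fell again (-2.01 ± 0.17, at least 2.98-fold lower, adjusted p = 0.0245), and Bhmt passed (adjusted p = 0.00747) while below background in both groups. With normexp the bounds of Ctse (+0.83), Chil1 (+0.46) and Kcnc2 (-0.46) were not reached and these 3 calls were lost, with adjusted p of 0.343, 0.343 and 0.417. Casq1 also lies on chromosome 1, at 194 tested genes from Tnnt2.

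Under the scanner-file record these genes showed no such difference at 1 week: Myh7 stood at +0.04 ± 1.02 (adjusted p = 0.996), Ctse at +0.49 ± 1.49, Cntn2 at -0.07, Rab7b at +0.12, Chil1 at -0.17, Casq1 at -0.23 and Kcnc2 at +0.22. The single gene that passed was the uncharacterised 4930503E14Rik, at +3.01 ± 0.21 (adjusted p = 0.0430; both KI arrays above both WT arrays), outside the naming rule and named after its value was seen; it did not meet the signal filter in the value-table record. Those with the smallest p, none past the threshold, were the cytokine receptor Il22ra1 (+1.58 ± 0.19), the flagellin receptor Tlr5 (+1.49 ± 0.18), Uts2b (at least 2.34-fold), Rbakdn (at least 2.13-fold), Camk1d (+1.102), Slc35d1 (+0.99), Spaca7 (+0.76) and Car13, which was below background. On the lower side were Svs6 (-3.63 ± 0.37, at least 2.92-fold), the mitochondrial peptidase Mipep (-1.22 ± 0.14), Uck1 (-0.99 ± 0.12), Casp14 (at least 1.97-fold), Serpina3h (-1.04), Idh3a (-0.80 ± 0.12), Zfp651 (-0.84) and Mccc1os. The bounds of Uts2b (+0.48), Rbakdn (+0.40), Svs6 (-0.83) and Casp14 (-0.48) were not reached with normexp.

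Over all genes, 1 of 15757 passed at 1 week in the scanner-file record with limma (1555 at an unadjusted p under 0.05 against 788 by chance). In the value-table record 8 of 15744 passed, 5 higher and 3 lower (1113 against 787), and no gene was called in both. Leaving out array C raised the scanner-file count to 265, leaving out A, B or D gave 43, 49 and 43, and leaving out any birth array gave 0. By the value table, the count without A, B, C or D was 66, 45, 42 or 64, and without a birth array 3 or 4. Myh7 kept its call in that record under 18 of 19 alternatives, with adjusted p from 2.5e-05 to 0.113. The adjusted p ranged from 0.00423 to 0.343 for Ctse, 0.00507 to 0.343 for Chil1, 0.0103 to 0.204 for Casq1, 0.0226 to 0.593 for Cntn2, 0.0146 to 0.288 for Rab7b, 0.00315 to 0.417 for Kcnc2 and 0.00807 to 0.616 for Bhmt.

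**Figure D2:**
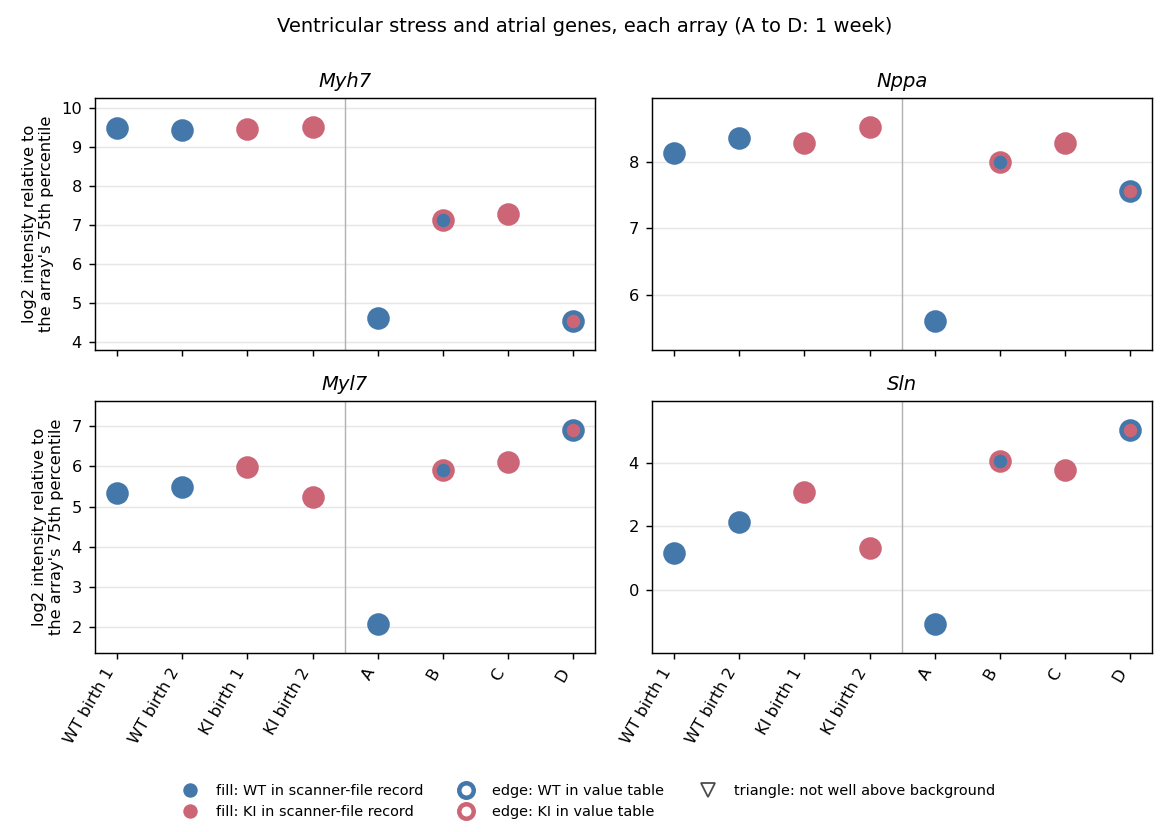
Log2 signal relative to the array's 75th percentile of Myh7 and of the atrial genes Nppa, Myl7 and Sln on each of the 8 arrays, with fill for the genotype by scanner file and edge for that by value table. Myh7 was between 9.44 and 9.52 on the birth arrays and at 4.61, 7.12, 7.28 and 4.54 on arrays A, B, C and D; Myl7 was at 2.08, 5.90, 6.10 and 6.91.

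The cardiac stress and fetal genes passed with camera as a list in KI at 1 week in the value-table record. The median was +0.42, with 27 of 31 positive and Myh7 alone passing over all genes and adjusted over the list alone (camera adjusted p = 6.4e-07; adjusted p = 0.334 with an estimated correlation; fry adjusted p = 0.0442). Nppa was at +1.56 ± 0.55, Nppb at +0.54 ± 0.21, the stretch-responsive Ankrd1 at +0.80 ± 0.25, Tnnt1 at +0.49 and Uchl1 at +0.64, none of which passed. Cell cycle genes had a median of +0.50 with 66 of 69 positive (camera adjusted p = 1.3e-14; adjusted p = 0.576 with an estimated correlation), and none passed. Examples were Kif20a (+0.88), Ube2c (+0.70) and Mki67 (+0.40). Sarcomere genes (+0.21; 0.00121) included Myoz1 at +0.87 ± 0.14, and 2 members were higher adjusted over the list alone against 1 over all genes. Fatty acid oxidation genes (-0.10; 0.011) included Pdk4, an inhibitor of pyruvate use, at -0.88 ± 0.22 and the uncoupling proteins Ucp2 (-0.50) and Ucp3 (-0.55). Inflammation genes had a median of -0.10 (0.0425). These 3 lists had adjusted p from 0.334 to 0.652 with an estimated correlation. Sarcomere lost its call without array B (0.162) or D (median -0.01; 0.353), and fatty acid oxidation without A (median +0.05; 0.796) or C (0.169). Inflammation lost it without B (0.162), C (0.111), D (0.487) or KI birth replicate 1 (0.0650) or 2 (0.0605). The stress-response genes Mthfd2 (+0.94 ± 0.19) and Manf (+0.63) did not pass.

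Marker levels differed between the 1-week arrays in both records. In the scanner-file record adipocyte markers had a median of +2.64 in KI against WT and atrial markers +0.69, with Ucp1 at +4.70 ± 1.89, Adipoq at +2.97 ± 1.13, Myl7 at +2.51 ± 1.09 and Sln at +2.91 ± 1.54. Epicardial (+0.40), erythroid (+0.28), endothelial (+0.16), fibroblast (+0.13) and macrophage (-0.17) markers also passed with camera, and these 7 lists had adjusted p from 0.541 to 0.618 with an estimated correlation. Under the value-table record the lists past camera were lymphocyte (-0.34), liver (-0.45), endothelial (-0.25), macrophage (-0.24), mural (-0.20) and erythroid (+0.49), with adjusted p from 0.529 to 0.713 with an estimated correlation. The atrial median there was +0.15 and the adipocyte median +0.82, and neither passed. Array A held the least atrial and adipocyte signal of the 1-week arrays and array D the most.

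Under the scanner-file record sarcomere genes had a median of -0.17 at 1 week (camera adjusted p = 1.7e-04), fatty acid oxidation -0.19 (1.7e-04), oxidative phosphorylation -0.14 (2.0e-05), glycolysis -0.10 (0.0394) and extracellular matrix +0.07 (0.0239). Members were the ubiquitin ligase Trim63 (-0.79 ± 0.17), the acyl-CoA dehydrogenase Acadm (-0.50 ± 0.12), the brain glycogen phosphorylase Pygb (-1.14 ± 0.27) and the elastic fibre genes Eln (+1.02) and Fbln1 (+0.78 ± 0.16). No member passed over all genes, 1 oxidative phosphorylation gene was lower adjusted over the list alone, and adjusted p ranged from 0.786 to 0.835 with an estimated correlation. These are the arrays whose atrial and adipocyte markers differed in the scanner-file record. Without array D sarcomere (-0.06; 0.0811), glycolysis (+0.01; 0.958) and extracellular matrix (+0.04; 0.754) lost their calls. Without array A fatty acid oxidation (0.180), oxidative phosphorylation (0.0661), glycolysis (0.334) and extracellular matrix (0.0661) did, and glycolysis also without WT birth replicate 2 (0.0502). The sarcomere, glycolysis, oxidative phosphorylation and extracellular matrix medians had the opposite sign in the value-table record, at +0.21, +0.13, +0.04 and -0.06; of these sarcomere passed there, and glycolysis (0.138), oxidative phosphorylation (0.856) and extracellular matrix (0.222) did not. Cell cycle (+0.02; 0.717) and inflammation (+0.07; 0.583), called by the value table, did not pass in the scanner-file record. Without array C the cell cycle median turned to -0.37 there. Stress and fetal genes had a median of +0.01 in the scanner-file record while the test pointed down, without passing (0.717).

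Of the 20 panel genes Myh7 passed at 1 week, in the value-table record. Elsewhere values are given for the scanner-file and then the value-table record. The remaining stress genes were Nppa at +1.12 ± 0.70 and +1.56 ± 0.55, Nppb at -0.20 and +0.54, Ankrd1 at -0.46 and +0.80 and Acta1 at -0.56 and +0.36. The potassium channel genes were Kcnip2 at -1.42 ± 0.40 and -0.25 and Kcnd2 at -0.44 and -0.95 ± 0.24, with Hcn4 at -0.00 and +0.57. Of the calcium genes, Pln was at -0.62 ± 0.18 and +0.26, Atp2a2 at -0.27 and -0.09 and Ryr2 at +0.03 and -0.15. Myh6 was at +0.05 and -0.32, Gja1 at -0.35 and +0.24, Tnni1 at +0.12 and +0.25, Tnni3 at -0.11 and +0.01, Postn at +0.28 and +0.09 and Col1a1 at +0.40 and +0.04. Ppargc1a was at +0.33 and -0.27, Cpt1b at +0.17 and -0.03 and Mki67 at +0.18 and +0.40. Other probes pointed the other way for Gja1 (0.52), Ryr2 (-0.55), Tnni1 (-0.48), Ppargc1a (-0.13) and Atp2a2 (0.01) in the scanner-file record, and for Gja1 (-0.50), Ryr2 (0.48), Col1a1 (-0.06) and Tnni3 (-0.02) in the value-table record.

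**Figure D3:**
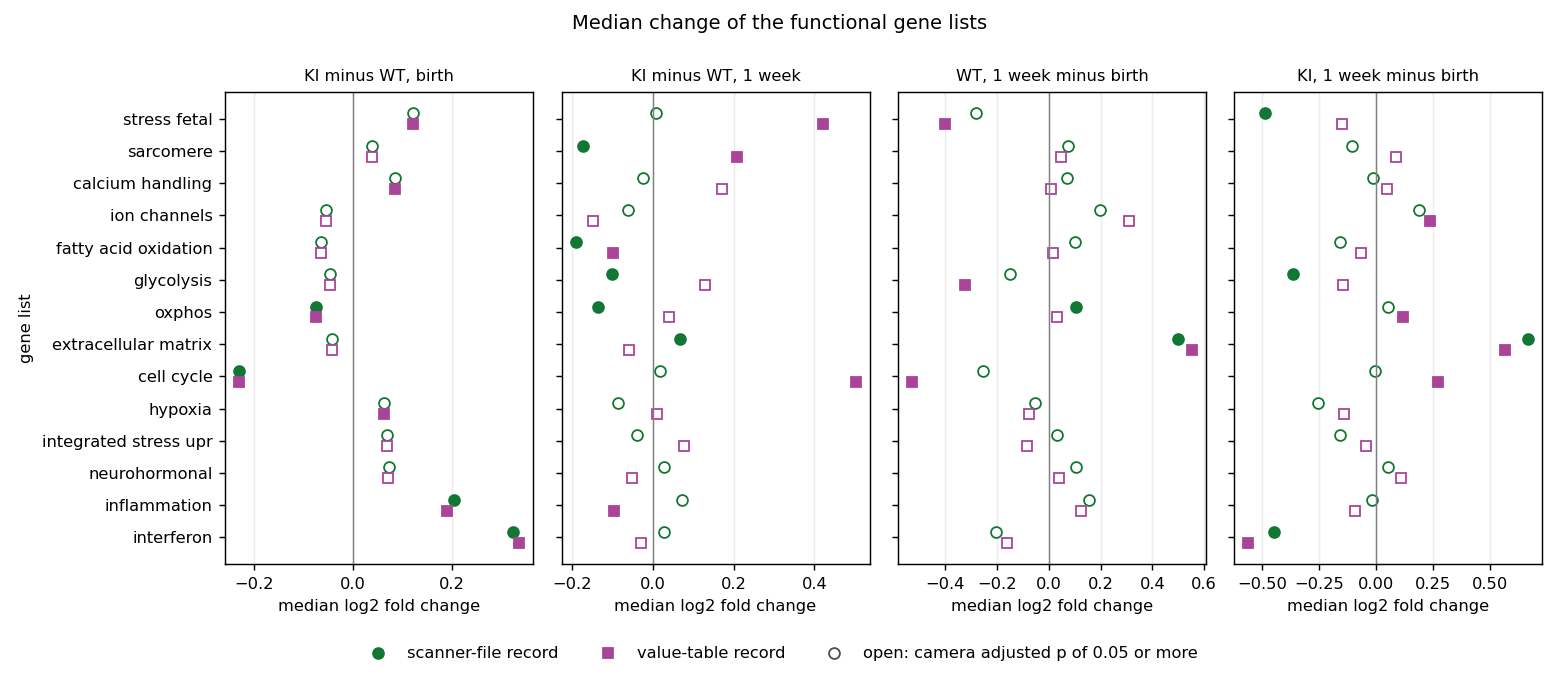
Median log2 difference of the measured members of each of the 14 functional lists in 4 comparisons, with circles for the scanner-file record and squares for the value-table record; open symbols did not pass with camera at the preset correlation. Cell cycle genes at 1 week stood at +0.02 in the scanner-file record and +0.50 in the value-table record.

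Age by genotype asked whether the KI minus WT difference itself changed over the first week. With the value-table samples, Myh7 passed, though not with the replicate block, with the difference +2.60 ± 0.17 larger at 1 week than at birth (adjusted p = 0.0222). It lost this call under 4 of 18 alternatives, with adjusted p from 5.8e-04 to 0.106. Next came Trpv6 (+2.58), Wfdc18 (+1.74), Angptl1 (+1.11) and Gpr149 (+1.09), and, lower, the neutrophil receptor Cxcr2 (-2.28), Ly6d (-1.84), Bin2 (-2.00) and Ren1 (-2.44), none of which passed. Trpv6 was dim at birth, so the size of its value depends on the processing. Cell cycle (+0.71; 7.6e-20), stress and fetal (+0.22; 0.0093), sarcomere (+0.14; 0.0136), inflammation (-0.16; 0.00136) and interferon genes (-0.29; 4.4e-09) passed with camera, with adjusted p from 0.190 to 0.829 with an estimated correlation. Stress and fetal genes lost the call without array A (0.0543), WT birth replicate 1 (0.1701) or KI birth replicate 1 (0.0874), and sarcomere without B (0.280), D (0.366) or WT birth replicate 2 (0.0586). Of the interferon genes 1 was lower adjusted over the list alone and 0 over all genes. Neutrophil (-0.52), lymphocyte (-0.69), macrophage (-0.35), platelet (-0.34) and mural (-0.23) markers passed camera beside them, all at an adjusted p of 0.410 with an estimated correlation.

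In the scanner-file record 0 genes passed age by genotype with limma (991 at an unadjusted p under 0.05 against 788 by chance), and leaving out any 1 array gave from 13 to 37. In the value-table record the count was 1 (763 against 787), and 19 to 44 with any array left out. Trpv6 (+2.57 ± 0.28, dim at birth), Il22ra1 (+2.26), Tmprss9 (+2.47), Wfdc18 (+1.97) and Chrm1 (+1.51) had the smallest p on the higher side and the dim H2-Aa and Nkg7, Uck1 (-1.29), Usp18 (-1.14 ± 0.16) and Ifitm6 (-1.21) on the lower. The interferon list (-0.27; 4.3e-07), sarcomere (-0.24; 0.00291), extracellular matrix (+0.14; 0.00633), cell cycle (+0.23; 0.00633) and hypoxia (-0.22; 0.0147) passed with camera, with adjusted p from 0.343 to 0.840 with an estimated correlation. The cell cycle median turned to -0.10 without KI birth replicate 2 and to -0.19 without array C, and its call was lost without A (0.0784) or WT birth replicate 1 (0.0928). Sarcomere (0.169) and extracellular matrix (0.438) lost theirs without D, and hypoxia without A (0.0889), D (0.102), WT birth replicate 1 (0.0928) or KI birth replicate 2 (0.745). By the value table, extracellular matrix (+0.08; 0.947) and hypoxia (-0.07; 0.133) did not pass, and stress and fetal genes (-0.12; 0.179) and inflammation (-0.04; 0.260) did not pass here. Marker lists that passed camera beside them were neutrophil (-0.59), platelet (-0.44), macrophage (-0.36), fibroblast (+0.26), endothelial (+0.19), atrial (+0.96) and adipocyte (+2.56), with adjusted p from 0.627 to 0.695 with an estimated correlation. Of the interferon genes 2 were lower adjusted over the list alone.

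WT 1 week against birth described the normal first week. Many extracellular matrix genes rose: 20 of 64 were higher and 4 lower over all genes, 29 and 6 adjusted over the list alone, with a median of +0.50 in the scanner-file record. Col8a1, a short-chain collagen, rose by 2.78 ± 0.21 (adjusted p = 0.00131) and the proteoglycan Lum by 1.49. The glycolytic aldolase Aldoc fell by 3.32 ± 0.27 and the glucose transporter Slc2a1 by 2.03 ± 0.32, whereas Gpd1, which feeds glycerol phosphate, rose by 2.18 ± 0.14. Among members of the stress and fetal and fatty acid oxidation lists, neither of which passed in this record, the slow skeletal troponin I gene Tnni1 fell by 1.21 ± 0.14, the ketone-body enzyme gene Bdh1 fell by 3.45 ± 0.31 and the metallothionein Mt2 fell by 3.004 ± 0.39, while Xirp2 of the intercalated disc rose by 3.15 ± 0.23. All of these had both 1-week arrays beyond both birth arrays.

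Over all genes 1994 passed in WT in the scanner-file record with limma, 1100 higher and 894 lower, 979 of them at least 2-fold. By the value table, 2990 passed, 1577 higher and 1413 lower, and 1662 genes were called in both records, all in the same direction. Both records use the WT birth arrays and array A here, which favours such agreement. Genes with large rises were Tuba8 (+4.43 ± 0.19), Klhdc8a (+4.23 ± 0.29) and, from a birth level below background, Itgb6, a subunit of an integrin that activates TGF-beta (at least 20.6-fold), Pcp4 (at least 14.9-fold) and Ptpn20 (at least 5.23-fold). Another Itgb6 probe was at +2.95. Genes with large falls were Hif3a, of the hypoxia-inducible factor family (-5.52 ± 0.35), and, to a level below background, the urinary protein genes Mup19 (at least 25.2-fold), Mup18 (at least 13.5-fold) and Mup17 (at least 9.91-fold) and the ammonium transporter Rhcg (at least 11.5-fold). Under the value-table record the rule named Tuba8 (+4.33) and, from below background, Efhd1 (at least 18.7-fold), Pcp4 (at least 18.7-fold), Itgb6 (at least 12.9-fold) and Colec10 (at least 4.42-fold) among rises, and Hif3a (-5.42) and, to below background, Mup19 (at least 21.9-fold), Mup18 (at least 11.8-fold), Rhcg and Mup17 among falls. None of these bounds was reached with normexp, under which the smallest value was +1.08 (Colec10) and the largest -2.77 (Mup19 in the scanner-file record); Ptpn20 lost its call there (adjusted p = 0.1004). Myh7 fell by 4.89 ± 0.12 (adjusted p = 2.6e-05) in the value-table record and stood at -3.60 ± 1.02 (adjusted p = 0.0656) in the scanner-file record. Without 1 of the WT arrays the scanner-file count was 593 (A), 783 (B), 818 and 594 (birth replicates 1 and 2). With the value-table samples, it was 1675 without D and 1198 and 1311 without birth replicates 1 and 2.

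The extracellular matrix list passed with camera in WT (adjusted p = 5.9e-06; adjusted p = 0.186 with an estimated correlation; fry adjusted p = 0.00475), and fibroblast markers passed camera beside it (median +0.76, 7 of 12 higher; adjusted p = 0.635 with an estimated correlation). Mural markers also passed (median +0.30, 3 higher and 1 lower of 12, camera adjusted p = 0.0362, adjusted p = 0.688 with an estimated correlation). Ion channel genes had 8 members higher and 2 lower, with the potassium channel Kcnj14 at +1.54 ± 0.12, and passed with fry (adjusted p = 0.00475) but not with camera (0.0967). Oxidative phosphorylation passed with camera (+0.11; 0.046; adjusted p = 0.892 with an estimated correlation), with Ckmt2, the mitochondrial creatine kinase, at +1.49 ± 0.16. This call was lost without array A (0.421), WT birth replicate 2 (0.298) or KI birth replicate 1 (0.0609) or 2 (0.0597), and by the value table (+0.03; 0.443). Other lists did not pass in the scanner-file record. Their counts, higher then lower, were 8 and 1 for sarcomere, 1 and 5 for stress and fetal genes, 2 and 3 for calcium handling, 4 and 3 for fatty acid oxidation, 4 and 7 for glycolysis, 4 and 4 for hypoxia and 2 and 3 for integrated stress. For neurohormonal genes they were 3 and 9, for inflammation 3 and 2, for interferon 3 and 8 and for cell cycle 0 and 0 (median -0.25). Adjusted over the list alone, the largest differences from these were 4 and 13 for interferon, 6 and 12 for glycolysis and 8 and 10 for neurohormonal genes. Irf7 fell by 0.86 ± 0.11 whereas Irf1 rose by 1.15 ± 0.14 among interferon genes, and Pdk1 fell by 0.89 among hypoxia genes, with another probe at 0.05. In the value-table record stress and fetal genes (-0.40; 0.00804), glycolysis (-0.32; 0.0306) and cell cycle genes (-0.53; 0.00288; 0 higher and 11 lower over all genes, 0 adjusted over the list alone) also passed with camera, with adjusted p from 0.4995 to 0.977 with an estimated correlation. Glycolysis (0.186) and cell cycle (0.0713) lost the call without array D, and stress and fetal genes (0.0547) and glycolysis (0.0544) without WT birth replicate 1.

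KI 1 week against birth described the first week in the mutant. Many extracellular matrix genes rose, with 29 of 64 higher and 4 lower (40 and 6 adjusted over the list alone) and a median of +0.67 in the scanner-file record. Many interferon genes fell, with 15 lower and 3 higher of 34 (17 and 3 adjusted over the list alone) and a median of -0.45. Irf7 fell by 1.27 ± 0.11 (adjusted p = 0.00229) and Usp18 by 1.17, and the endothelin gene Edn1 fell by 1.18 ± 0.15. Aldoc fell by 3.04, Bdh1 fell by 2.90 and Tnni1 fell by 1.11, and Col8a1 rose by 2.37. Ucp1, the uncoupling protein of brown fat, rose by 9.03 ± 1.89 (at least 126-fold; adjusted p = 0.0248) and Adipoq by 5.47 ± 1.13 (at least 9.90-fold; adjusted p = 0.0240). Both calls were lost without array D, where Ucp1 stood at 8.44 (adjusted p = 0.108) and Adipoq at 4.66 (adjusted p = 0.111), and in the value-table record (0.0781 and 0.117). They were also lost without KI birth replicate 1 (0.0986 and 0.0950) or 2 (0.116 and 0.114), without WT birth replicate 1 (0.0516 and 0.0502), with no filter on dim probes (0.0525 and 0.0512) and with array weights (0.137 and 0.119), the highest adjusted p of any alternative. With normexp and quantile normalization Ucp1 stood at 4.56 (adjusted p = 0.0127) and Adipoq at 1.54 (adjusted p = 0.0221), so the calls were kept but the lower bounds on the folds did not hold. Both genes also lay higher at 1 week in WT. There Ucp1 was at least 4.04-fold higher in the scanner-file record and at least 7.75-fold in the value-table record. Adipoq was at least 1.05-fold and 2.01-fold higher. With normexp these WT values were +1.66 and +2.65 for Ucp1 and +0.42 and +0.99 for Adipoq, and none passed.

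Over all genes 2403 passed in KI in the scanner-file record with limma, 1319 higher and 1084 lower, 1093 of them at least 2-fold; in the value-table record 1669 passed, 923 higher and 746 lower. The records shared 1467 of these genes, all in the same direction. Both records use the KI birth arrays and array C here, which favours such agreement. Besides Ucp1 and Adipoq, large rises in the scanner-file record were those of Car3 (+5.19, above background on 1 of 2 birth arrays), Tuba8 (+4.63 ± 0.19) and Itgb6 (at least 11.96-fold, another probe at +2.26). Large falls were those of Hif3a (-5.20 ± 0.35), Tent5b (-4.75), Slc10a6 (-4.25, above background on 1 of 2 arrays at 1 week), the peptide gene Calca (at least 6.39-fold) and Rhcg (at least 6.08-fold). By the value table, they were the rises of Tuba8 (+4.74), Cilp (+4.48, above background on 1 of 2 birth arrays), Itgb6 (at least 19.1-fold), Mas1 (at least 6.50-fold) and Meig1 (at least 5.33-fold) and the falls of Hif3a (-5.30), Slc10a6 (-4.18), Calca (at least 7.34-fold), Rhcg (at least 6.98-fold) and the decoy receptor Il1r2 (at least 6.39-fold). None of these bounds was reached with normexp, under which the values lay between 0.95 (Meig1) and 2.06 (Itgb6) in size, and all these genes kept their calls. Myh7 fell by 2.29 ± 0.12 (adjusted p = 3.6e-04) in the value-table record and stood at -3.58 ± 1.02 (adjusted p = 0.0604) in the scanner-file record. Without array C the scanner-file count was 4216, and it was 1256 without D, 1535 without A, 1588 without B and 949 and 661 without birth KI replicates 1 and 2. The value-table count was 655 without B, 707 without C and 889 and 660 without birth KI replicates 1 and 2.

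The extracellular matrix (camera adjusted p = 6.8e-10), interferon (2.3e-05), stress and fetal (-0.49; 0.0252) and glycolysis (-0.36; 0.0223) lists passed in KI in the scanner-file record, with adjusted p of 0.074, 0.293, 0.917 and 0.917 with an estimated correlation. The last 2 lost their calls without array D (0.196 and 0.0885) or KI birth replicate 2 (0.0503 and 0.0981), and by the value table (-0.15 and -0.15; 0.0635 and 0.0689). Fibroblast (+0.95, 9 of 12 higher), endothelial (+0.48, 6 of 12 higher), mural (+0.57, 5 higher and 2 lower of 12) and adipocyte markers (+4.65, 5 of 10 higher) passed camera beside them, with adjusted p from 0.403 to 0.624 with an estimated correlation. Of the neutrophil markers 8 of 11 fell (median -2.33; -1.62 and 8 of 11 in WT). Under the value-table record extracellular matrix (+0.57; 9.3e-09), interferon (-0.56; 5.9e-07; 1 higher and 16 lower), ion channels (+0.24; 0.0217), oxidative phosphorylation (+0.12; 0.00753) and cell cycle genes (+0.27; 0.00416) passed, with adjusted p from 0.322 to 0.964 with an estimated correlation. Ion channels lost the call without B (0.140) or KI birth replicate 1 (0.0670), oxidative phosphorylation without B (0.075), and cell cycle without C (0.355) or KI birth replicate 2 (median -0.06; 0.762). Lists with no camera call in the scanner-file record had counts, higher then lower, of 4 and 2 for sarcomere, 2 and 6 for calcium handling, 7 and 0 for ion channels, 2 and 4 for fatty acid oxidation, 4 and 2 for oxidative phosphorylation and 2 and 0 for cell cycle. They were 1 and 6 for hypoxia, 2 and 2 for integrated stress, 5 and 8 for neurohormonal genes and 6 and 4 for inflammation. Adjusted over the list alone, they became 5 and 8 for sarcomere, 11 and 2 for ion channels and 2 and 9 for hypoxia. The medians of cell cycle (-0.01) and inflammation (-0.02) lay below 0 while their tests pointed up, without passing. Over all comparisons the median, mean and test of a list differed in sign 9 times in each record, none of them past camera. No list called by camera in any of the 5 comparisons kept its call with an estimated correlation in either record, and fry called 6 lists in the scanner-file record and 11 in the value-table record.

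The changes of the first week were largely shared by the genotypes. Under the scanner-file record 1335 genes passed in both WT and KI, all in the same direction, against 304 if the lists were independent (761 higher against 92.1 and 574 lower against 61.5; Pearson r across genes 0.787). With the value-table samples, the number was 1409 against 317, with r 0.799. Genes are not independent replicates. These contrasts share no array, but both compare the same 2 rows of the slide, so an effect of row would enter both alike. Arrays B and D change genotype between the records. If either record gave the right samples, the 1-week groups of the other mixed the genotypes, which favours agreement there.

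The maturation overlap asked whether genes that differed in KI at 1 week were those that change in WT over the first week. In the value-table record 3 of the 5 genes higher in KI, Myh7 among them, fell with age in WT, against 0.449 expected of independent lists, and 0 rose, against 0.501. Of the 3 lower in KI 2 fell, against 0.269, and 1 rose, against 0.3005, so the lower genes did not mirror the higher ones, and these expected counts leave out the shared arrays. The contrasts share the WT 1-week arrays with opposite sign, which alone gives a negative correlation. Pearson r across 15744 genes was -0.418 in the value-table record, against -0.165 in 100 simulations of an unchanged KI group, and the covariance was -0.0899 against -0.0277. In the scanner-file record r was -0.169 against a simulated -0.173, and the covariance was -0.0350 against a simulated range of -0.0321 to -0.0231. With a separate WT array in each contrast r was -0.0430 and -0.160 in the value-table record and -0.00739 and -0.0441 in the scanner-file record, which are values with no test.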

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

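The 7 tests of explanations in this part were chosen after the results they bear on were seen. The difference in Myh7 between KI and WT changed with age by 2.6024 (log2) in the value-table record, which marked it for a closer look because the genotype effect differed between the ages by the interaction test.

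The pattern with most bearing on the study is that arrays B, C and D stand under different samples in the scanner files and in the value table. Genes near Tnnt2 that differ at birth, where the records give the same samples, offer a test. The region was chosen after 1-week calls in the value-table record were seen, and the signal filter also used the 1-week arrays. Chil1 and Cntn2, called in that record at 1 week, are among the genes used, which favours it. In a limma fit of the birth arrays alone, 10 of the 100 nearest genes had an unadjusted p below 0.01, with a median difference of 0.974 in size. At 1 week, provided that such differences persist with age, the test is their median difference signed by its direction at birth: it was 0.584 in the value-table record, with 8 of 10 in the same direction (range -0.857 to 2.15), which is consistent with scanner files attached to the wrong samples; by the scanner files it was -0.0946, with 2 of 10 in the same direction (range -0.445 to 0.222), which argues against wrong columns in the value table. On a scale on which the WT birth arrays lie at 0 and the KI birth arrays at 1, the median over these genes was 0.098 on array A, 0.944 on B, 0.790 on C and 0.186 on D, whereas over the 234 genes on other chromosomes with such a p at birth the signed median at 1 week was 0.0535 in the value-table record and 0.003 in the scanner-file record. On the slide, arrays A to D lay in columns 1 to 4. With the scanner-file samples this repeats the birth order, WT in columns 1 and 2 and KI in columns 3 and 4. With the value-table samples it does not, a point for the scanner files that was not tested. No biological explanation was tested, and the assignment stays a hypothesis because the genotype itself was not read from the samples.

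The genes that differed between genotypes lay close to Tnnt2 more often than others. At birth, in a limma fit of the birth arrays alone, 10 of the 100 nearest tested genes on chromosome 1 had an unadjusted p below 0.01, against 251 of 15656 others. The odds ratio was 6.82 (95% confidence interval 3.12 to 13.3, Fisher's exact p = 6.1e-06, 2-sided). It describes the pattern and supports no explanation, since genes that prompted it are among the 10 and neighbouring genes are not independent. A candidate explanation is DNA of another mouse strain carried along with the knock-in, which needs the same differences at 1 week: the signed median of 0.584 in the value-table record and -0.0946 in the scanner-file record leaves it open, because the samples of these arrays are in doubt. Variants under single probes would leave other probes of a gene unchanged, and in 5 of 6 genes with another measured probe all probes pointed the same way, which is too few to exclude them. An effect of the mutant troponin on these genes in the heart cannot be told apart from linked strain DNA in these groups.

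Myh7 and Nppa lay higher in KI at 1 week in the value-table record. The levels argue against more atrial tissue on the KI arrays as the source for Myh7: array D, a WT array in that record with more of the atrial gene Myl7 than either KI array, had Myh7 2.58 (log2) below the lower KI array. For Nppa the same gap was 0.44, against 1.96 between the WT arrays, so atrial tissue cannot be told apart from a genotype effect. A slower fall of the fetal programme in the KI ventricle may also be involved: of the 7 other stress and fetal genes that fell with age in WT, 6 lay above 0 in KI against WT at 1 week. Most members of the whole list also lay above 0 in that record, so this count does not set the falling genes apart. This comparison shares the WT arrays with the choice of genes, which favours values above 0, and the list lost its call with an estimated correlation, so it stays open.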

How the results depend on the processing

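The value table as a source of values and the other alternatives were chosen before the data were examined, except the alternatives run within the value-table record, the probes without a symbol and the crossed replicate numbers, which were added after seeing the data. Unless stated, the cause of a change was not tested. A slide or row block was not run, and only-the-arrays-compared gives no value for age by genotype. With an array left out, its group's lone array is assumed to vary like the other groups. Of the single-gene values, 7200 kept direction and side of the threshold in the scanner-file record, 54 gained and 216 lost a call; in the value-table record 6663 kept both, 64 gained and 251 lost a call and 3 reversed. Of the list values 1343 kept both, 88 gained, 84 lost and 11 reversed in the scanner-file record, and 1296, 56, 99 and 5 in the value-table record. For the scanner-file record, the count in WT over the first week (1994) became 979 at 2-fold, 1257 with no filter on dim probes and 3627 with array weights, and the count in KI (2403) became 1093, 1521 and 1120, and 850 with only the arrays compared. The 1 gene of KI against WT at 1 week became 0 with normexp, no filter, the filter on all 8 arrays, the eBayes trend, array weights, the mean of probes, only the arrays compared, the replicate block and the crossed replicate block. It became 2 with median scaling, 3 with probes without a symbol and 8 with the value table. The count at birth (0) became 1 with median scaling and 6 with the value table, and age by genotype (0) became 1 with the value table. For the value-table record, the count in WT (2990) became 1294 at 2-fold, 1870 with no filter, 1905 with array weights and 1697 with only the arrays compared, and that in KI (1669) became 900 at 2-fold and 1092 with no filter. The 6 genes at birth became 1 with normexp, 0 with no filter, 3 with the filter on all 8 arrays, 0 with only the arrays compared, 0 with the replicate block and 2 with probes without a symbol. The 8 at 1 week became 5 with normexp, 3 with no filter, 4 with the filter on all 8 arrays, 4 with array weights, 3 with the mean of probes and 0 with only the arrays compared. The 1 of age by genotype became 0 with quantile normalization, 2 with median scaling, 0 with no filter, 2 with the filter on all 8 arrays, 0 with the replicate block and 0 with probes without a symbol. Crossing the replicate numbers as a block gave 0 genes at 1 week in the scanner-file record (0 with the same-number block, 0 with none) and 1796 in KI in the value-table record (812 with the same-number replicate block, 1659 with none), each with only the arrays compared but the genes tested with all 8 arrays; with genes filtered on the arrays compared, the count without a block was 1731. List calls (20) became 32 with normexp, 0 with an estimated correlation and 6 with fry; in the value-table record (26) they became 0 and 11. The maturation correlation (-0.169) became -0.418 in the value-table record and -0.0074 and -0.0441 with separate WT arrays, and the value-table one became -0.0430 and -0.160. Leaving out 1 array at a time gave, in the scanner-file record, 0 to 37 genes at birth (18 the lowest without a birth array), 0 to 265 at 1 week, 13 to 37 for age by genotype, 593 to 2826 in WT, 661 to 4216 in KI, 13 to 24 lists and a correlation of -0.399 to -0.0277. For the value-table record it gave 1 to 40 at birth, 3 to 66 at 1 week, 19 to 44 for age by genotype, 1198 to 4200 in WT (1675 without D), 655 to 1944 in KI, 20 to 31 lists and -0.636 to -0.275. Reversed genes, all in the value-table record, were Adipoq at 1 week (-1.75, range to 3.92) and Myl7 in WT (1.496, range from -3.34), both without WT 1-week replicate 1, and Cxcl12 in KI (-0.0331) with the mean of probes. With the value table the 1-week medians of sarcomere (0.209), glycolysis (0.130), extracellular matrix (-0.0586) and inflammation genes (-0.0950) changed sign, as did that of oxidative phosphorylation. In age by genotype the medians of stress and fetal (0.224) and sarcomere genes (0.141) changed sign. The stress and fetal median at 1 week lay above 0 in both records (0.421 with the value table), and only the direction of its test reversed. The cell cycle median reversed without KI birth replicate 2 at birth (0.120, range from -0.565) and in age by genotype (-0.1001), and without KI 1-week replicate 1 at 1 week (-0.365, range to 0.431) and in age by genotype (-0.188, range to 0.634). It reversed in the value-table record without KI birth replicate 2 at birth (0.120, range from -0.565) and in KI (-0.0585, range to 0.655), as did hypoxia at birth (-0.0616, range to 0.324). In that record the fatty acid oxidation median (0.0511, range from -0.255) reversed at 1 week without WT 1-week replicate 1. The oxidative phosphorylation median (0.146, range from -0.123) stayed above 0 there, as with all arrays. Myh7 at 1 week lost its call in that record only with the arrays compared alone (adjusted p = 0.113, of a range from 2.5e-05). Signal over background limits genes such as Trpv6, Ctse, Bhmt and Ucp1, whose folds against a dim group depend on the processing. Of 60 bounds given as at least a fold, 57 were not reached with normexp and quantile normalization together, and 15 under another alternative.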

Other observations

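The values in this part were chosen after the results were seen, apart from the marker lists, which were fixed before the data were examined. Neutrophil genes fell over the first week in both genotypes, 8 of 11 in each, while the list lost its camera call with an estimated correlation (adjusted p = 0.635 in WT and 0.403 in KI in the scanner-file record, 0.494 and 0.508 in the value-table record). S100a8, S100a9 and Retnlg changed by -1.63, -1.62 and -2.82 (log2) in WT and by -2.82, -2.60 and -3.71 in KI in the scanner-file record, the siderophore-binding Lcn2 by -1.60 and -1.88 and the collagenase Mmp8 by -1.85 and -2.33; all of these passed in the value-table record too. Of single genes, Nos2 rose by 1.55 in WT and 1.54 in KI (1.63 and 1.46 in the value-table record), and the chemokine Cxcl9 was at least 4.15-fold higher in WT, having been below background at birth, a bound not reached with normexp (+0.94). Lymphocyte and thymus markers had a median of +0.69 in WT (camera adjusted p = 0.00448; adjusted p = 0.688 with an estimated correlation) and +0.42 in KI (0.128) in the scanner-file record, and +0.90 (7.7e-05; 0.494 with an estimated correlation) and +0.28 (0.261) in the value-table record. Macrophage markers had +0.56 (0.00862; 0.635 with an estimated correlation) and +0.15 (0.640), against +0.56 (0.0127; 0.514 with an estimated correlation) and +0.25 (0.261). Age by genotype gave camera adjusted p of 0.0646 for the lymphocyte and 0.00561 for the macrophage list in the scanner-file record (0.695 and 0.627 with an estimated correlation), and 4.6e-09 and 0.00518 in the value-table record (0.410 for both with an estimated correlation).

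Markers of adipose and atrial tissue differed between the single arrays of 1 week. The adipocyte markers, relative to their mean over all arrays, stood at -1.33, 1.51, 1.93 and 3.33 on arrays A, B, C and D and between -1.24 and -0.598 on the birth arrays, and the atrial markers at -0.391, 0.428, 0.257 and 0.659. Schwann and neural markers passed camera over the first week, with a median of +0.49 in WT (3 of 9 higher) and +0.73 in KI (4 of 9 higher) in the scanner-file record (camera adjusted p = 0.0144 and 0.00304; 0.635 and 0.403 with an estimated correlation). By the value table, the medians were +0.86 (4 of 9 higher) and +0.80 (3 of 9 higher; 0.00205 and 0.00829; 0.494 and 0.508 with an estimated correlation). Skeletal muscle markers stood at -0.13 in WT and -0.78 in KI in the scanner-file record and -0.22 and -0.36 in the value-table record. They passed camera only in KI in the scanner-file record (3 of 10 lower, camera adjusted p = 0.0489, adjusted p = 0.403 with an estimated correlation). Marker lists that did not pass over the first week in WT in the scanner-file record were cardiomyocyte (+0.01), erythroid (+0.03), lung epithelium (+0.07), platelet (+0.30), epicardial (-0.22), atrial (-0.16), endothelial (+0.19), adipocyte (+0.78) and liver (-1.12); of these, endothelial (+0.40; 0.0112) and adipocyte markers (+1.69; 0.041) passed camera in the value-table record, with adjusted p of 0.514 and 0.639 with an estimated correlation.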
